A study of Mus musculus with 6 samples.

How the data were processed

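The data are RNA-seq gene counts of 6 libraries of sorted mouse hematopoietic stem cells, 3 aged and 3 young. Per the labels' protocols, libraries were made from total RNA with the SMART-Seq v4 kit, which amplifies full-length cDNA from few cells, and sequenced on an Illumina HiSeq as single reads of 51 cycles. This kit does not mark strand, so reads of a gene and of an antisense gene over the same bases cannot be told apart. Per the submitters' processing notes, the tools were Trimmomatic, STAR 2.6.0, HTSeq 0.11.1 and edgeR with the mouse genome build mm10; the notes give no roles, order or settings. The annotation and the counting mode are not given in the sources used here. The authors deposited 1 table of whole-number counts per gene, with coordinates, strand, length in kb and a description; the counts carry no scaling. All 6 count columns were matched to samples by name, and no per-sample column was left unused. Starts in the table equalled those of a RefSeq table of the same build for 14475 of 23349 matched symbols and lay 1 below for 17, so coordinates were read as 1-based. Mitochondrially encoded protein genes, a list fixed beforehand, were not analysed here.

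Groups and replicate numbers came from the sample titles. Replicate numbers run from 1 to 3 in aged and from 4 to 6 in young samples and pair nothing. Totals ran from 16452829 to 21918658 counts, and 3 counts, the limit that a count of 0 allows, correspond to 0.132 to 0.239 CPM. Such limits cover counting error only, since PCR copies are not independent molecules.

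Differences were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, estimateDisp, glmQLFit with its defaults and glmQLFTest, with Benjamini-Hochberg adjustment over 13413 genes and a threshold of 0.05. The genes tested held 99.92% of the counts. All 6 libraries entered a single fit with age as the only term. Log2 fold changes are aged minus young, given with their standard errors or as linear folds; fitted folds can differ slightly from the ratio of the mean CPM. CPM values are TMM-scaled, given as mean ± SD over 3 libraries, and no pseudocount was added to them.

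Gene lists were written before the data were examined. They cover genes often reported higher in stem cells of old mice, stem cell identity, lineage priming, cell cycle, metabolism, stress, inflammation, signalling, chromatin, reported miR-126 targets and markers of other cell types. None was chosen on these samples. Lists with at least 3 tested genes were ranked against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over 31 lists. Fewer than 3 B-lineage markers were tested, so that list had no camera test.

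The genes named in the text followed a rule set before the data were examined: the 10 higher and 10 lower genes with the smallest p, groups that do not overlap, at least 5 CPM in the higher group and a regular gene symbol; up to 4 called members of each list, or 2 uncalled ones; the sort markers, Egfl7, Xist and 4 Y-linked genes. Members of lists with larger p were left out for length, and a few other genes are not reported here. Osmr, Gpr183, Actb, Cd34 and the genes named only in the closing section were added after their values were seen.

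The fit and the list test were tested on counts simulated for 13413 genes with the means and depths of these libraries, 3 against 3. Of 98 genes changed 4-fold, 79.6% were recovered, and of 100 genes changed 2-fold, 11.0%. Of the unchanged, 4 genes and 0 of 30 lists were called. Genes were drawn independently and these lists at random, so the list test was not tried on genes that vary together. In this setting, where few genes were changed, changes near 2-fold were often missed. Many may be missed in the data too, but the share can differ there, where 772 genes were called.

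Alternatives were median-ratio, upper-quartile or no scaling, no filter or at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, a likelihood ratio test, robust empirical Bayes, thinning to the smallest library, removal of genes above 1% of a library, each library left out, and a test against a fold of 1.5. For lists, an estimated correlation, fry and a prior count of 0.5 were tried. A correction for GC content and length (splines with 4 degrees of freedom, GC content from GENCODE transcripts), a fit with both young 4 and aged 2 left out and edgeR's newer quasi-likelihood method were added after seeing the data.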

Results

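The series measured RNA of hematopoietic stem cells (HSCs), the rare bone marrow cells that renew all blood lineages, from young and old mice. Its title places the work in a study of miR-126, a microRNA of blood vessel and stem cells, and of the ageing marrow. The cells had been sorted as lineage-negative, Sca-1 and c-Kit positive, CD150 positive and CD48 negative. Aged cells came from mice of 20 months (3 libraries, here aged 1 to aged 3) and young cells from mice of 2 months (3 libraries, young 4 to young 6). Aged samples were pooled from 4 mice and young samples from 30 mice. The labels leave open whether these numbers hold for each sample or for the group together, so p-values measure the spread between pools, which may be partly technical. Gene counts summed to between 16452829 in young 4 and 21918658 in young 6. The table listed 24091 genes, of which 13413 had enough counts to be tested.

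Genes of the sort were measured first, with genes that tell the sex of the mice. Y-linked Ddx3y, Eif2s3y and Uty had 0 counts in all 6 libraries, and Kdm5d had 1 count, in aged 2. A count of 0 allows up to 0.132 CPM (counts relative to library size) in young 6 and up to 0.239 CPM in young 4, at 3 counts each. Xist, the RNA that coats the silenced X chromosome of females, stood at 147 ± 32.1 CPM in aged and 132 ± 8.04 CPM in young libraries (SD, n = 3 each). This is the pattern of female cells in both groups. Kit, which encodes c-Kit, stood at 976 ± 99.0 CPM in aged and 632 ± 282 CPM in young cells, with an adjusted p of 0.305. Slamf1, which encodes CD150, stood at 98.8 ± 18.9 and 64.3 ± 1.95 CPM, with an adjusted p of 0.0891. Ly6a, which encodes Sca-1, rose 3.04-fold in aged cells, from 39.9 ± 9.58 to 121 ± 50.8 CPM. Cd48, the marker that the gate excludes, was low in both groups and fell 7.72-fold, from 10.8 ± 3.17 CPM in young to 1.40 ± 1.04 CPM in aged libraries. The calls of Ly6a and Cd48 had adjusted p-values of 0.0435 and 0.0345, and each was lost without any of aged 2, aged 3, young 5 or young 6, and that of Ly6a also without aged 1. The fall of Cd48 was 13.2-fold without aged 1.

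Young 4 stood apart from young 5 and young 6. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.966 to 0.983 between aged libraries and 0.989 between young 5 and young 6. It was 0.951 between young 4 and young 5, and 0.948 between young 4 and young 6. Between ages it ran from 0.883 (aged 1 and young 4) to 0.953 (aged 2 with young 5 or young 6), so young 4 was no closer to its group by this measure than young 5 was to aged 2. No pair agreed within sampling noise: chi-square per degree of freedom was 11.2 for young 5 and young 6, the closest pair. Actb, which encodes beta-actin, took 4.06% of the counts of young 4 and 0.555% to 1.36% of those of the other 5 libraries. Aged 2 had counts in 20918 genes, against 16084 to 17057 in the other libraries.

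**Figure D1:**
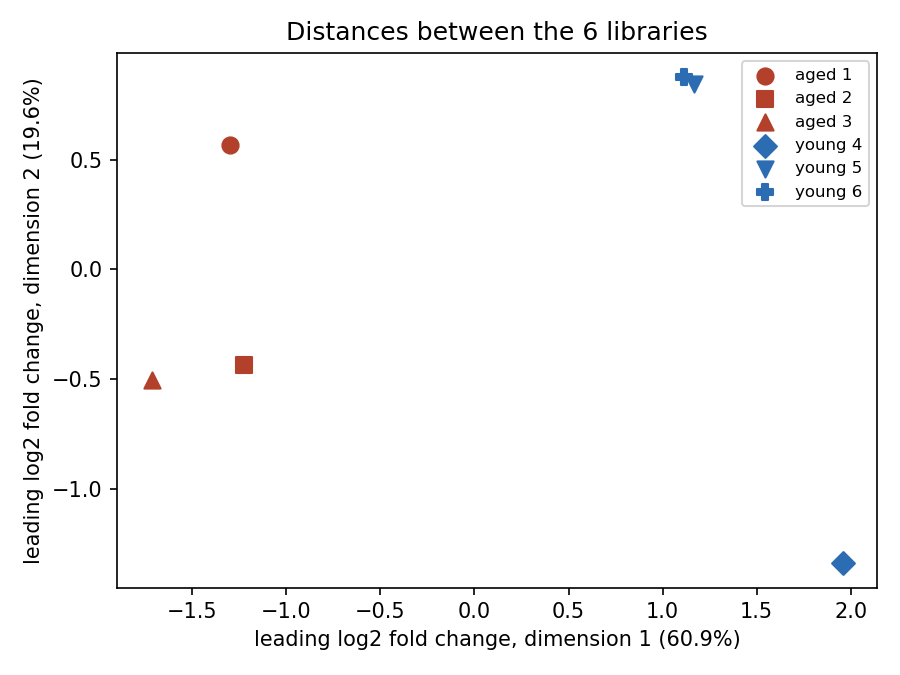
Multidimensional scaling of the 6 libraries, from the 500 genes that differ most between each pair; axes are leading log2 fold changes, and each point is a library, coloured by age. The first dimension (60.9% of the variance) separates the 3 aged from the 3 young libraries, and the second (19.6%) separates young 4 from young 5 and young 6.

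The comparison of aged with young HSCs asked which genes differ with age. Old stem cells had far more RNA of Rorb, Plscr2, Aldh1a1, Selp and Gpr183. Klf4, Ebi3, Cd48 and the early lymphoid genes Flt3 and Satb1 were lower, as were 9 of 28 genes of DNA replication and 8 of 24 of mitosis. These 2 lists ranked lower by camera, but with an estimated correlation their adjusted p was 0.539. With a library left out, Flt3 and Satb1 each kept their call in 1 of 6 runs and Cd48 in 2. In all, 772 of the 13413 genes passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, on which counts of called genes rest unless another tool is named: 571 were higher and 201 were lower in aged cells. Of these, 522 higher and 166 lower genes changed at least 2-fold, and 298 and 43 at least 4-fold. The aged and young values did not overlap for any of the 772 genes; such separation held for 36.6% of all tested genes, where chance gives 10%.

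The number of calls depended on the libraries used: it was 282 without aged 1, 129 without aged 2, 85 without aged 3, 74 without young 5 and 88 without young 6. It was 1029 without young 4, and 650 (434 higher, 216 lower) with both young 4 and aged 2 left out, 423 of them among the 772. Higher genes made up 74.0% of the calls. With each library's trend by GC content and length taken out, 1379 genes were called and the split was 694 higher to 685 lower, or 50.3% higher. Of 78 called genes picked by the rule for named genes, 62 lost their call without at least 1 library (59 without young 5, 6 without young 4), and none changed sign. The other 16 kept it with each library left out: Rorb, Plscr2, Aldh1a1, Clca3a1, Tm4sf1, Wwtr1, Aspa, Cysltr2, Mab21l2, Prtn3, Alcam, Jam2, Bmpr1a, Klrb1c, Ebi3 and Klf4. Leaving out 1 library moved the fold by over 1.5 times for 8 of the 82 called genes checked: H2-Eb1, Itgam, Cd48, Bmp4, Ibsp, Cldn5, Ramp2 and Mt2.

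Among the higher genes, the smallest p belonged to Rorb, a nuclear receptor of the ROR family (mm10 chromosome 19, 18930609 to 19111196, minus strand). It stood at 98.5 ± 17.5 CPM in aged and 1.29 ± 0.0593 CPM in young cells, a 75.7-fold rise (log2 fold change 6.24 ± 0.23 SE, adjusted p = 0.000254 by edgeR's quasi-likelihood test). Plscr2, a phospholipid scramblase gene (chromosome 9, 92275602 to 92297752, plus strand), rose 32.7-fold, from 7.59 ± 1.57 to 248 ± 27.3 CPM (adjusted p = 0.00065). Aldh1a1, an enzyme that makes retinoic acid (chromosome 19, 20601982 to 20643462, plus strand), rose 8.92-fold, from 14.5 ± 1.40 to 130 ± 9.92 CPM (adjusted p = 0.000867). Clca3a1 rose 7.63-fold to 449 ± 14.5 CPM; its interval overlaps its paralog Clca3a2 on the same strand, so reads of the pair may be split or lost. Tm4sf1, a membrane protein gene, rose 16.3-fold, and Wwtr1, which encodes the Hippo pathway coactivator TAZ, rose 15.8-fold. Both lie on chromosome 3, 57287064 to 57301919 and 57455644 to 57575910. Aspa, which encodes aspartoacylase, rose 5.57-fold, the leukotriene receptor gene Cysltr2 5.84-fold and Prtn3, a granule protease gene, 4.26-fold. Mab21l2 was at 43.7 ± 10.2 CPM in aged cells and 0.0771 ± 0.0686 CPM in young cells, below what 3 counts give, so no fold is printed. It lies inside Lrba on the opposite strand, and the kit does not mark strand.

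Among the lower genes that met the naming rule, the smallest p belonged to Ebi3, a subunit of the cytokines IL-27 and IL-35 (chromosome 17, 55952623 to 55957022, plus strand). It fell 3.64-fold, from 44.1 ± 3.32 CPM in young to 12.1 ± 0.337 CPM in aged cells (adjusted p = 0.00381). Its interval overlaps Gm16712, an antisense gene. Klf4, a transcription factor gene (chromosome 4, 55527137 to 55532475, minus strand), fell 5.74-fold, from 75.7 ± 12.7 to 13.2 ± 3.72 CPM (adjusted p = 0.00607). Ctla2a, which encodes a protease inhibitor, fell 3.52-fold from 626 ± 130 CPM. Ppbp, a chemokine of platelets, fell 4.48-fold, and Ncf4, a subunit of the phagocyte NADPH oxidase, fell 4.45-fold. Tpm4, a tropomyosin gene, fell 2.16-fold, Kif23, a kinesin of cell division, 2.54-fold, Jakmip1 3.00-fold and Ptgr1, which encodes prostaglandin reductase, 2.89-fold. Rps4l fell 3.49-fold, but it is a near copy of another ribosomal protein gene and overlaps Tmtc1, so its reads are uncertain.

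**Figure D2:**
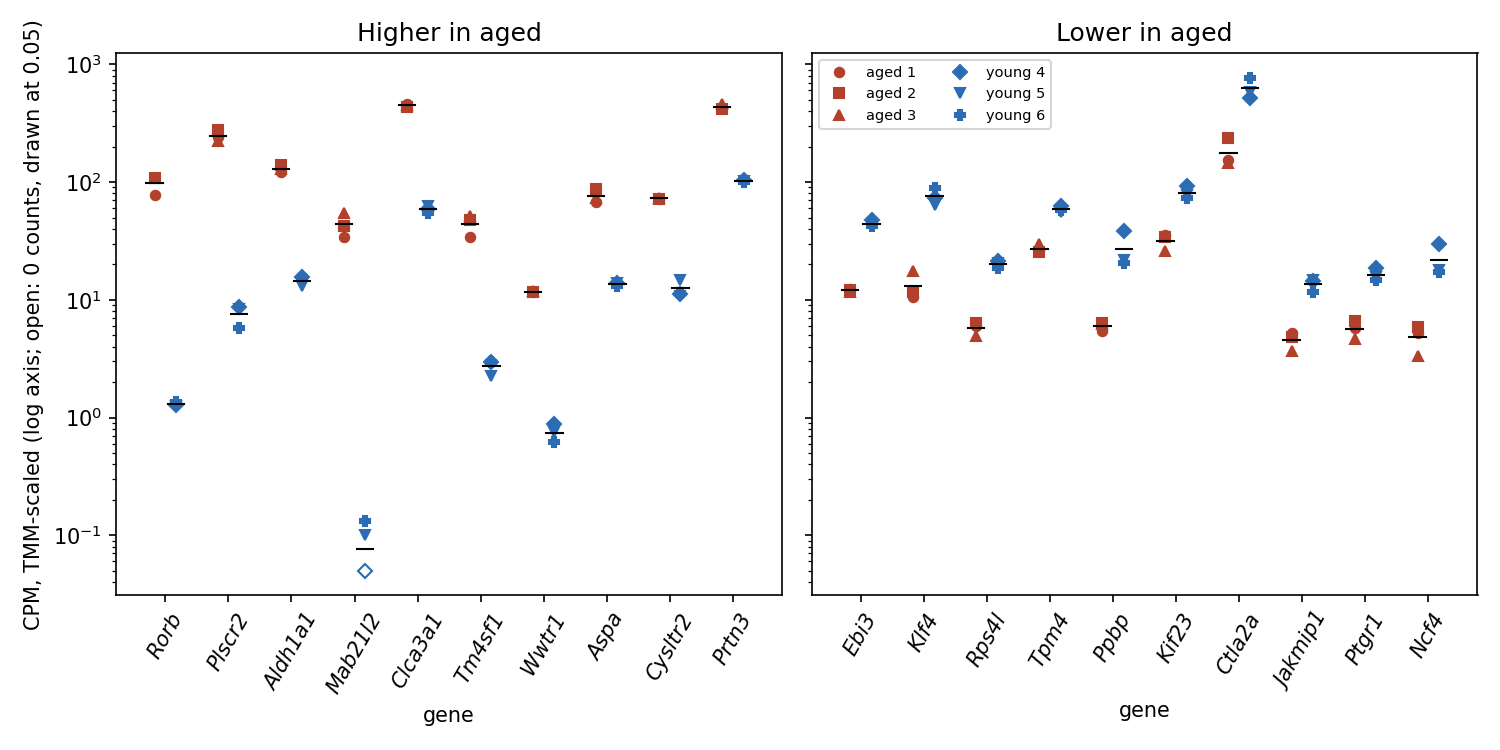
TMM-scaled CPM on a log axis of 10 higher and 10 lower genes in each of the 6 libraries. They had the smallest p among called genes with non-overlapping groups, at least 5 CPM in the higher group and a regular symbol. Short black lines are group means (n = 3). Rorb lies at 98.5 CPM on average in aged and 1.29 CPM in young libraries, and Ebi3 at 12.1 and 44.1 CPM.

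Most genes that are often reported higher in stem cells of old mice rose here. Of the 38 genes on this list, 29 rose, none fell and 9 did not pass the test; adjusted over the list alone, 37 rose. Their median log2 fold change was 2.14. Osmr, a subunit of the oncostatin M receptor, went from 0.473 ± 0.196 to 23.3 ± 7.71 CPM, and Gpr183, a receptor for oxysterols, from 1.32 ± 0.690 to 58.2 ± 22.6 CPM. Selp, which encodes P-selectin and overlaps the antisense gene Gm16548, rose 11.0-fold, and Clu, which encodes clusterin, rose 4.45-fold. The list ranked above all other tested genes (camera adjusted p = 2.72e-25; adjusted p = 0.231 with an estimated correlation). With single libraries left out, the number that rose ranged from 13 without aged 3 or young 5 to 31 without young 4.

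Genes of long-term stem cell identity also ranked higher in aged cells, with 5 of 27 members called higher and 1 lower (10 adjusted over the list alone, 9 higher and 1 lower). Procr, which encodes the endothelial protein C receptor, rose 2.82-fold, from 40.2 ± 2.40 to 114 ± 19.9 CPM. Fgd5 rose 2.11-fold, the homeobox gene Hoxb5 2.03-fold and Ly6a 3.04-fold. Procr kept its call in 4 of 6 runs with a library left out, Fgd5 and Ly6a in 1 and Hoxb5 in 0. The list's adjusted p was 0.0191 by camera and 0.539 with an estimated correlation. It was 0.0565 without aged 3, 0.0521 without young 5 and 0.0518 with the GC and length trend taken out.

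Some genes of cell division were called lower in aged HSCs. Of 24 genes of G2 and mitosis, 8 fell and none rose, and all 24 fell adjusted over the list alone; their median log2 fold change was -1.83. Cdc20, an activator of the anaphase-promoting complex, fell 3.30-fold, from 251 ± 35.6 to 75.9 ± 28.4 CPM. Cenpe and Cenpf, which encode kinetochore proteins, fell 3.80-fold and 3.95-fold, and Tpx2, a spindle protein gene, 3.75-fold. Of 28 genes of DNA replication, 9 fell and none rose (22 lower adjusted over the list alone), with a median of -1.09. Mcm4, a subunit of the replicative helicase, fell 2.11-fold, from 308 ± 29.3 to 146 ± 22.8 CPM, Cdc45 2.49-fold, Gins2 2.42-fold and Cdc6 2.55-fold. Of 33 DNA repair genes, 3 fell and none rose (10 lower adjusted over the list alone), among them Brca2 2.07-fold and Chek1 3.45-fold.

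The mitosis, replication and repair lists ranked below other genes, with camera adjusted p-values of 2.84e-15, 2.11e-13 and 1.49e-05, each 0.539 with an estimated correlation. The median deviation of the mitosis genes from their mean over libraries was -1.898 in aged 3, against -0.372 in aged 1 and -0.568 in aged 2. In young 4 it was 1.33, against 0.847 and 0.783 in young 5 and 6. Of the mitosis genes, 5 were called lower without young 4, 1 without aged 1, and 0 without any of aged 2, aged 3, young 5 or young 6. In each of these fits the list's median stayed between -2.09 and -1.48, and all 24 were lower at an unadjusted p under 0.05. With all 6 libraries, DESeq2 called 24 mitosis and 20 replication genes lower, and limma-voom 18 and 9. Of the replication genes, 10 were called lower without young 4 and 0 by edgeR without any of the other libraries, where 20 to 27 were lower at an unadjusted p under 0.05. Of the repair genes, 3 were called lower without young 4 and 0 without any of the others, where 8 to 15 were lower at an unadjusted p under 0.05. With the trend of GC content and length taken out, 23 of the 24 mitosis genes and 24 of the 28 replication genes were lower.

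**Figure D3:**
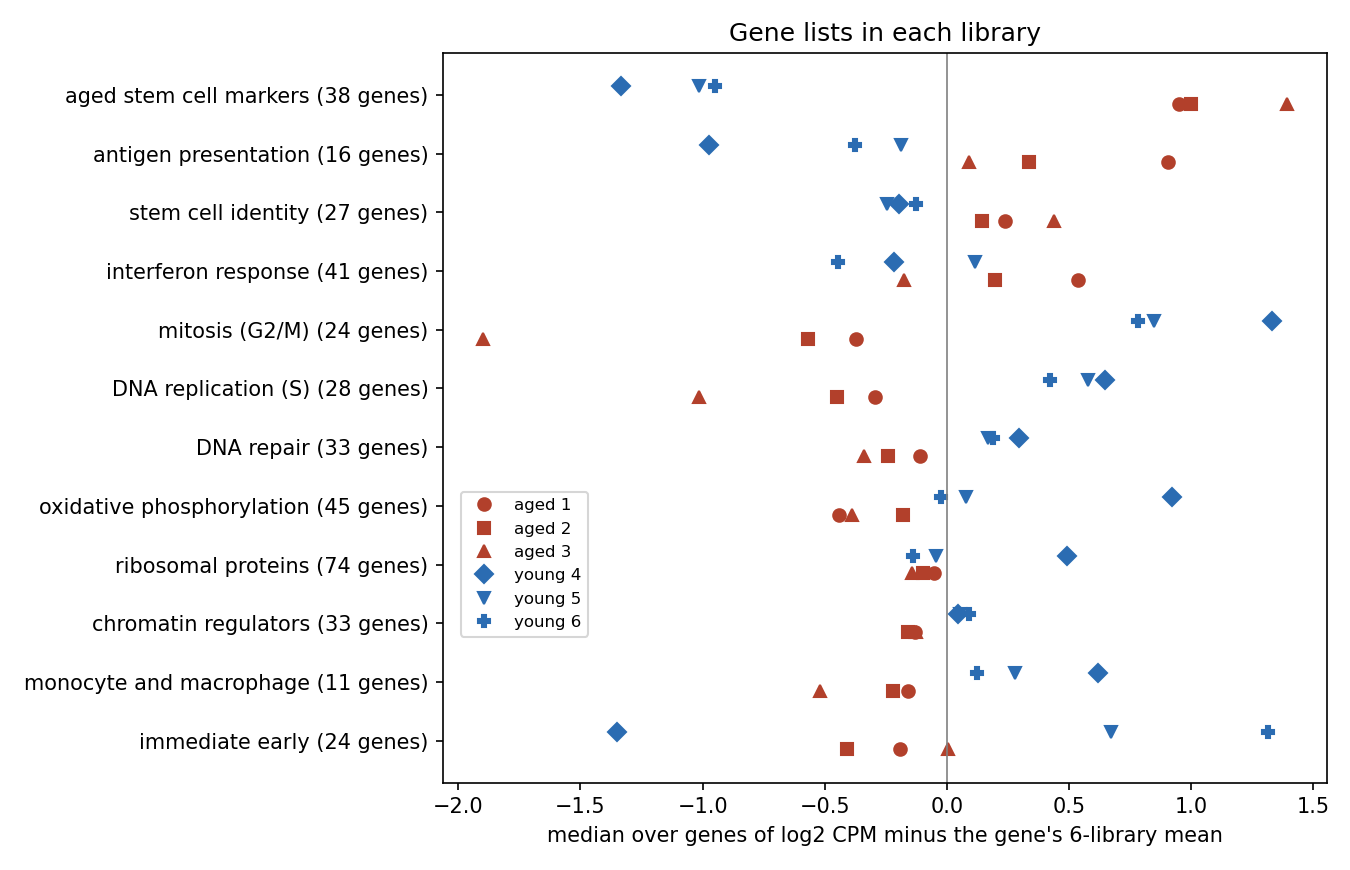
Median over the genes of 12 lists of the log2 CPM in a library minus the gene's mean over the 6 libraries, by library; red points are aged and blue points young libraries. The mitosis list lies between -1.898 and -0.372 in aged and between 0.783 and 1.329 in young libraries, while the immediate early list is at -1.351 in young 4 and at 0.671 and 1.313 in young 5 and young 6.

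Of the genes of MHC class II, which presents peptides to T cells, 4 on the antigen presentation list were called higher in aged cells. Cd74, the invariant chain, rose 6.08-fold, from 146 ± 45.1 to 888 ± 468 CPM, H2-Aa 5.69-fold, H2-Ab1 4.51-fold and H2-Eb1 8.80-fold (15.5-fold without young 5). The intervals of H2-Eb1, H2-Aa and H2-Ab1 overlap in the table, so their reads are uncertain. These 4 were the only called genes of the 16 tested on that list, whose other class II genes did not pass, and 10 rose adjusted over the list alone. The list ranked above other genes (camera adjusted p = 3.03e-05; adjusted p = 0.539 with an estimated correlation). Its median deviation was -0.975 in young 4, lower than -0.190 in young 5 and -0.377 in young 6, and it was 0.906 in aged 1, 0.334 in aged 2 and 0.092 in aged 3. Cd74 likewise stood at 981 and 1300 CPM in aged 1 and aged 2 and at 380 CPM in aged 3. Of the list, 1 member was called without young 4, 3 without aged 3 and 0 without aged 1, aged 2, young 5 or young 6.

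Interferon response genes ranked slightly higher as a list (camera adjusted p = 0.0308; adjusted p = 0.824 with an estimated correlation), and 0 of the 41 were called by edgeR's quasi-likelihood test. At an unadjusted p under 0.05, 8 were higher and 1 lower; DESeq2 called 3 higher and 1 lower and limma-voom 0 (with quality weights, 3 and 1). Gbp3, a guanylate-binding protein gene, was at 147 ± 37.3 CPM in aged and 68.2 ± 14.3 CPM in young cells (adjusted p = 0.0539). The list's call was lost without aged 1 (0.462), aged 2 (0.0778) or young 6 (0.44), without a filter on low counts (0.109) and with both young 4 and aged 2 left out (0.0857). Of 26 inflammatory genes, 2 rose and none fell (3 higher adjusted over the list alone): Bcl3, an NF-kB cofactor gene, 7.68-fold and Cd14, the endotoxin co-receptor gene, 2.90-fold. Without young 4, 3 were higher and 4 lower, and limma-voom with quality weights called 5 higher and 5 lower. That list's camera adjusted p was 0.185, but 0.00953 at 5 CPM or more and 0.0402 with the GC and length trend taken out.

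Lineage genes moved in both directions. Of 22 platelet and megakaryocyte genes, Selp and Clu rose while Ppbp and Rab27b fell (2.06-fold); adjusted over the list alone 5 rose and 2 fell, and camera gave an adjusted p of 0.977. Of 17 genes of granulocyte and monocyte progenitors, Prtn3 and Csf3r, the receptor for G-CSF (3.07-fold), rose and Nkg7 fell 4.02-fold; adjusted over the list alone 2 rose and 4 fell (camera adjusted p = 0.721). Of 15 lymphoid priming genes, 3 fell and none rose. They were Flt3, a cytokine receptor gene of early progenitors, 2.37-fold (17.1 ± 4.40 to 7.24 ± 0.705 CPM), Satb1, a chromatin organiser gene, 2.24-fold, and Cd52 5.16-fold. Flt3 and Satb1 kept their call in 1 of 6 runs with a library left out, and Cd52 in 0. DESeq2 called 1 other member higher, 1 rose and 3 fell adjusted over the list alone, and camera gave an adjusted p of 0.240.

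Respiratory chain genes encoded in the nucleus ranked lower in aged cells, with a median log2 fold change of -0.73 over 45 genes, 44 of them negative (camera adjusted p = 1.73e-09; adjusted p = 0.554 with an estimated correlation). None was called by edgeR's quasi-likelihood test, over all genes or adjusted over the list alone; 26 were lower and 0 higher at an unadjusted p under 0.05, DESeq2 called 7 lower and limma-voom 0 (19 with quality weights). Cox5a, a subunit of cytochrome c oxidase, was at 111 ± 10.3 CPM in aged and 194 ± 42.9 CPM in young cells (adjusted p = 0.0661). The median deviation of this list was 0.921 in young 4 against 0.0790 in young 5 and -0.0250 in young 6. Without young 4 the list's median was -0.35, it still ranked lower (camera adjusted p = 3.79e-09) and edgeR called 3 members lower. Ribosomal protein genes had a median of -0.22 over 74 genes (camera adjusted p = 0.00064; adjusted p = 0.824 with an estimated correlation). This call was lost without young 4 (adjusted p = 0.277) and with the GC and length trend taken out (0.257), and 0 members were called by edgeR, DESeq2 or limma-voom or had an unadjusted p under 0.05. Rpl28 was at 146 ± 4.34 CPM in aged and 195 ± 38.7 CPM in young cells.

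Several stress genes were called higher in aged cells. Of 25 antioxidant and metal response genes, 4 rose and none fell, also adjusted over the list alone: the metallothionein genes Mt1 (3.55-fold) and Mt2 (5.67-fold; 8.66-fold without young 5), the sulfiredoxin gene Srxn1 (2.30-fold) and Gpx3, a glutathione peroxidase gene (17.8-fold, from 3.32 ± 2.49 to 61.0 ± 22.9 CPM). DESeq2 called 1 member lower, limma-voom with quality weights 5, and edgeR 1 without young 4. Mt1 and Mt2 kept their call in 2 of 6 runs with a library left out, and Srxn1 and Gpx3 in 1. Of 21 heat shock and unfolded protein genes, 2 rose, the small heat shock protein gene Hspb1 11.1-fold and Trib3 4.02-fold, the same number as adjusted over the list alone. Hspb1 was low, at 0.383 ± 0.179 CPM in young and 4.17 ± 1.5 CPM in aged cells. Hspb1 kept its call in 3 of 6 runs with a library left out, and Trib3 in 1. Of these 21, 14 had a negative sign; DESeq2 called 2 higher and 3 lower, and limma-voom with quality weights 3 higher and 7 lower. Of 21 p53 targets and cell-cycle inhibitors, Perp rose 3.87-fold and Cdkn2c, which encodes p18, rose 2.67-fold (5 adjusted over the list alone). For this list DESeq2 called 5 higher and 1 lower, and limma-voom with quality weights 7 higher and 3 lower. Of 26 glycolysis and hypoxia genes, Aldoc (1.91-fold) and Epas1, which encodes HIF-2 alpha (4.64-fold), rose, also adjusted over the list alone. Of 24 autophagy and lysosome genes, Lamp2 rose 1.75-fold (5 adjusted over the list alone). Perp kept its call in 4 of 6 runs with a library left out, and Cdkn2c, Aldoc, Epas1 and Lamp2 each in 1. In the main fit none of these 5 lists passed; their camera adjusted p-values were 0.613, 0.374, 0.267, 0.264 and 0.185. The autophagy and lysosome list passed at 5 CPM or more (0.037).

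Chromatin regulators ranked slightly lower, with a median of -0.23 over 33 genes and a single member called, Satb1, which fell. The number was the same adjusted over the list alone. DESeq2 called 2 higher and 5 lower, limma-voom with quality weights 4 and 9, and edgeR without young 4 called 1 and 3. The list's camera adjusted p was 0.0264, against 0.539 with an estimated correlation and 0.0554 without aged 2. Of 24 immediate early genes, Klf4 fell and the others did not pass the test (2 lower adjusted over the list alone; camera adjusted p = 0.185). This list depended on single young libraries. Without young 4, 11 members were lower, the median log2 fold change was -1.18 instead of -0.77 and the camera adjusted p was 3.14e-07. Without young 6, 1 member was lower, the median was -0.189 and the camera adjusted p was 0.982. With all 6 libraries and no filter on low counts, the camera adjusted p was 0.0203. The list's median deviation was -1.351 in young 4, 0.671 in young 5 and 1.313 in young 6.

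Genes of the niche and vessel signals in the study's title changed singly. Egfl7, whose intron holds miR-126, stood at 104 ± 8.03 CPM in aged and 85.2 ± 20.0 CPM in young cells, with an adjusted p of 0.413. The entries Mir126a and Mir126b had 0 counts in every library; the kit primes on poly(A) tails, which mature microRNAs lack. Of 24 tested genes reported as miR-126 targets, Mertk, a receptor kinase gene, rose 3.58-fold and Adam9 rose 1.72-fold, while Cxcl12 fell 4.59-fold, from 3.92 ± 1.61 to 0.856 ± 0.393 CPM. Adjusted over the list alone 2 rose and 2 fell, and the camera adjusted p was 0.826. Of 21 genes of vessel growth, the Notch ligand gene Dll4, which overlaps the antisense gene Gm14207, rose 5.68-fold, and the count was the same adjusted over the list alone (camera adjusted p = 0.721).

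Of 22 genes of TGF-beta and BMP signalling, 3 rose and none fell. Bmpr1a, a BMP receptor gene, went from 0.645 ± 0.315 to 21.5 ± 3.22 CPM in aged cells. Bmp4 rose 12.7-fold (7.66-fold without aged 3; called in 2 of 6 runs with a library left out) and Id2, a target of BMP signals, 2.85-fold; adjusted over the list alone 3 rose and 2 fell. DESeq2 called 3 higher and 3 lower, and edgeR without young 4 called 4 higher and 2 lower. The list's camera adjusted p was 0.480, but 0.0245 at 5 CPM or more. Of 26 adhesion and homing genes, Jam2 (8.59-fold), Alcam (4.40-fold), Selp and the integrin gene Itgam (6.88-fold) rose. Itgam rose 3.95-fold without aged 1 and was called in 0 of 6 runs with a library left out. Cd34, a sialomucin gene, fell 1.73-fold, from 259 ± 22.6 to 150 ± 16.3 CPM, and was called in 1 of those 6 runs. Adjusted over the list alone 6 rose and 5 fell (camera adjusted p = 0.687).

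Markers of other cell types were mostly low and moved in different directions. Klrb1c, the NK1.1 antigen, which overlaps Klrb1b, rose 20.8-fold, from 7.55 ± 2.39 to 157 ± 47.1 CPM, while Cd4 fell 11.0-fold to 0.279 ± 0.119 CPM (3 T and NK genes tested; camera adjusted p = 0.815). Of 12 endothelial markers, Ramp2, from 0.519 ± 0.312 to 12.3 ± 7.70 CPM, and Cldn5 (8.06-fold; 5.17-fold without aged 3) rose (0.613; 0.0152 at 5 CPM or more). Of 9 stromal and bone markers, Ibsp, a bone matrix protein gene, fell from 6.52 ± 2.83 to 0.296 ± 0.266 CPM and Cxcl12 fell (0.185; 0.0344 without young 5 and 0.0199 without a filter). Padi4 rose 4.15-fold among 3 neutrophil markers (0.219), and Il4 fell 2.68-fold among 6 mast cell and basophil markers (0.129; 0.00133 without young 5 and 0.0338 with library totals).

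Adjusted over the list alone, the calls were 1 higher and 1 lower of the T and NK, 3 and 1 of the endothelial, 0 and 3 of the stromal, 1 and 0 of the neutrophil and 0 and 1 of the mast cell markers. Of 11 monocyte and macrophage markers, 0 passed edgeR's test, 3 were lower at an unadjusted p under 0.05, and DESeq2 called 2 lower and limma-voom 0 (2 with quality weights). Their list ranked lower in aged cells (camera adjusted p = 0.00574; adjusted p = 0.539 with an estimated correlation; 0.0565 without aged 3), and 2 fell adjusted over the list alone. Vcam1 was at 3.81 ± 1.37 CPM in aged and 8.88 ± 1.67 CPM in young cells. Of 11 erythroid markers, 0 passed edgeR's test, with 3 higher and 3 lower at an unadjusted p under 0.05; DESeq2 called 2 and 2 and limma-voom 0 (3 and 6 with quality weights). The hemoglobin gene Hba-a2 was at 32.4 ± 15.0 and 6.14 ± 5.08 CPM (adjusted p = 0.0737), and 3 erythroid markers rose adjusted over the list alone (camera adjusted p = 0.480). Of the B-lineage markers, Cd79a was at 0.716 ± 0.176 and 0.0703 ± 0.0662 CPM and Cd79b at 75.1 ± 14.9 and 94.9 ± 33.3 CPM, and neither was called by edgeR's quasi-likelihood test (adjusted p = 0.0525 for Cd79a). DESeq2, limma-voom and the likelihood ratio test each called Cd79a higher.

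Over all 31 lists tested with camera, 4 ranked higher and 7 lower in aged cells at an adjusted p of 0.05. With an estimated correlation 0 lists passed, and 2 had an unadjusted p under 0.05. By fry, which asks whether a list's genes move on balance in a single direction, 3 lists passed, and 22 passed its test for change in either direction.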

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

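The GC and length correction, the fit with young 4 and aged 2 left out and the adjusted-deviance method were chosen after seeing the data. All 772 called genes that an alternative tested kept their direction in it: none of the genes shared between calls changed sign. The number called was 761 with median-ratio scaling, 817 with limma-voom and 690 with robust empirical Bayes. Other settings moved it by over 1.5 times: 443 genes (363 higher, 80 lower) at 5 CPM or more, where fewer genes were tested; 1893 (1109, 784) with DESeq2; 1910 (1210, 700) with the likelihood ratio test; 4094 (2326, 1768) with limma-voom and quality weights; and 203 (190, 13) against a fold of 1.5, a stricter null. The GC and length correction gave 1379 genes, 685 of them lower. Lower genes numbered 133 with library totals and 342 without a filter. For the 5 CPM filter, the smaller number of genes tested was not the whole cause. Of the 772 genes, 560 were still tested there, and 438 were called. Apart from the test against a fold and the correction, the cause was not tested. With a library left out, calls ranged from 74 to 1029, higher genes from 71 to 679 and lower genes from 3 to 350. Fits that kept young 4 gave 74 to 282 calls, and the fit without young 4 gave 1029. With both young 4 and aged 2 left out there were 650, so the number of libraries alone did not set these counts. What keeping young 4 in a smaller fit does was not tested. Of 78 called genes that the naming rule picked, 16 kept their call with each library left out and 62 lost it at least once, 6 of them without young 4. Library totals moved the median of all genes to 0.20 log2 from 0.04, upper-quartile scaling to 0.11 and the GC and length correction to -0.08. Lists called numbered 9 to 12 of 31 or 32 across scalings, left-out libraries and no filter, and 15 of 28 at 5 CPM or more, but 0 with an estimated correlation and 3 with fry, which asks another question. Over 2056 verdicts on 94 named genes, 1619 kept their side of the threshold, 390 lost it and 44 gained it. Sign changed in 3, in genes that were not called: Cd79b was at 0.0697 and Xist at -0.00681 with quality weights, and Xist ran from -0.0375 without aged 1 to 0.242 without aged 3; the cause was not tested. The planned older form of the quasi-likelihood test is the default of the edgeR version used, so it is the reported fit. No paired analysis was possible because the aged and young groups share no replicate numbers. Depth was similar across libraries, and thinning to the smallest gave 760 genes.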

Other observations

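The tests on nuclear receptor and C-type lectin genes, on GC content and length in young 4, on the kind and depth of the reads of aged 2 other than their slope with gene length, on splits of the libraries and with a stricter rule for related neighbours were chosen after the results were seen. Of 32 nuclear receptor genes tested on a list of 40, 8 rose and none fell, 26 had a positive sign and the median log2 fold change was 0.63 (camera p = 2.42e-06, adjusted p = 9.7e-06 over the 4 lists added; p = 0.0659 with an estimated correlation). They included the progesterone receptor gene Pgr (1.96 ± 0.331 CPM in young, 18.0 ± 2.06 CPM in aged) and the retinoic acid receptor gene Rarb (12.7 ± 0.598 and 45.5 ± 15.4 CPM). Of 14 C-type lectin receptor genes tested, 5 rose and none fell: Klrb1c, Clec1a, Clec2d, Clec9a and Clec12b (camera p = 0.0125, adjusted p = 0.0166; p = 0.105 with an estimated correlation). Both lists were written because some of their genes had been seen to rise, so these p-values are no independent evidence for either group. Clec9a and Clec1a lie 1.9 kb apart on chromosome 6. Imprinted genes had been expected to be lower in aged cells. Among 19 tested, Ndn rose 2.67-fold (called in 1 of 6 runs with a library left out) and none of the others passed edgeR's test. Their median log2 fold change was 0.39 ± 0.20 (SE over genes), 12 had a positive sign and camera gave an adjusted p of 0.68, which lends the expectation no support. The bound set beforehand, a camera p of 0.05 or more, was too weak to exclude it, since such a p does not show that values did not differ, and the members went both ways.

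Genes that rose in aged cells lay beside each other more often than chance gives: 72 adjacent pairs of tested genes both rose, against a median of 24 in 10000 shuffles matched on expression (permutation test, p = 1e-04, the smallest they can give). Of these pairs, 13 overlapped and 21 more had symbols that begin with the same 3 letters, such as Hoxb9 and Hoxb8, Gbp9 and Gbp4, and Plscr1 and Plscr2. The other 38 pairs still exceeded the median of 20 in the shuffles (permutation p = 3e-04), but related genes such as Mt2 and Mt1 remained among them. With neighbours that share all letters before the first digit left out as well, 36 pairs remained against a median of 20 (permutation p = 0.001). Examples of the 36 are Tm4sf1 and Wwtr1, 153.7 kb apart, and Trpm6 and Rorb, 38.1 kb apart, and relatives with unlike symbols may be among the rest. A candidate explanation is shared regulation of neighbours, which was not tested. In the HoxB cluster on chromosome 11, Hoxb6 was at 7.35 ± 1.92 CPM in aged and 0.457 ± 0.258 CPM in young cells, and Hoxb7, Hoxb8 and Hoxb9 averaged 2.58, 1.38 and 2.02 CPM in aged cells and 0.202, 0.0731 and 0.0664 CPM in young cells.

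The mitosis and replication lists had lower medians in aged cells, and 3 technical explanations were tested. The median of the mitosis list stayed at -1.65 without young 4, at -1.62 or lower under 4 scalings and at -1.86 with GC content and length taken out, so none of these alone accounts for it. Multipotent progenitors in the young sort may contribute: the median of their markers was -0.66 ± 0.29 (SE over genes). Of these markers, Cd48, Flt3, Cd34, Satb1 and Tespa1 were called lower and Csf3r higher. Camera gave an adjusted p of 0.0105 over the 4 lists added, and a p of 0.0803 with an estimated correlation. All of the called markers but Tespa1 were also on lists reported above, so these p-values are not independent of those results. The sort excluded CD48-positive cells, and whether progenitors passed it was not tested, which leaves this explanation open. A difference in division with age also stays open, as untested by other means.

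Young 4 had less RNA of most immediate early genes than young 5 and young 6. These genes respond within minutes to handling or signals, and 23 of 24 lay below the mean of young 5 and young 6, with a median of -2.35 log2. Egr1 was at 67.6 CPM there against 465.9 and 893.9 CPM, and Cxcr4 at 764 CPM against 94.5 and 89.3 CPM. GC content and length of genes explained 25.2% of the variance of its deviations, so they are not the whole cause, and the immediate early genes stayed at -2.08 ± 0.35 with that trend taken out. A larger share of dividing cells could be part of it: its mitosis genes lay 0.486 ± 0.129 higher (SE over genes), too near the bound set to decide, and its replication genes 0.05. Handling of the sample was not recorded in the labels and stays open, as does a difference between pools of mice.

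Aged 2 held low counts of many genes silent elsewhere: of 4598 genes with 0 counts in the other 5 libraries it detected 2285, against 75 to 133 genes found only in each other library. These counts rose with gene length with a slope of 0.776 ± 0.0232 on the log scale, less than in proportion to length. Background from genomic DNA would also give a rise with length. The top 1% of these genes held 9.3 ± 0.46% of the counts, against 6.01% expected from length if reads were independent. PCR copies are not independent, so this excess cannot decide whether the counts were spread evenly by length. Depth is argued against, since its total was 84.9% of the highest, while genomic DNA and RNA of another cell type both stay open. Reads per kb were 1.02 on autosomes, 0.794 on the X and 0.0072 on the Y chromosome. The Y value does not bear on genomic DNA of these mice, since Xist and the Y-linked genes had the female pattern in both groups. These genes took 0.031% of its counts, and leaving out aged 2 with young 4 gave 650 called genes.

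Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave 772 called genes and the highest other gave 0; with 10 splits the share is never under 0.1, and the splits are too few to test for chance. At an unadjusted p under 0.05 the real split gave 3361 genes and the highest other 1676, for aged 1 with young 5 and young 6 against the rest. In that split aged 2, aged 3 and young 4 stand together. Across genes, which are not replicates, the deviations of young 4 and aged 2 from their group mates had r = 0.537, and each fell with GC content (Spearman -0.445 and -0.44).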
